A study of Homo sapiens with 12 samples.

How the data were processed

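Polyadenylated RNA was sequenced from HT1080 cells, a human fibrosarcoma line, that stably expressed dCas9, a cleavage-deficient Cas9 used in CRISPR interference. The cells also carried either a guide RNA against an LTR8B element, a long terminal repeat of an endogenous retrovirus, in the first intron of SP140, or a control guide RNA against GFP. Cells of each line were left untreated or treated with interferon beta (IFNB) at 10 U/mL for 4 h. The 12 libraries fell into 4 groups, with 2 libraries each for GFP untreated and GFP IFNB, and 4 each for LTR8B untreated and LTR8B IFNB. Libraries were made with a polyA mRNA kit and single or unique dual index adapters, per the labels' protocols, which do not say which library had which adapter, so no library batch was tested. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples.

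The deposited table of whole-number counts per gene was the starting point. Per the submitters' processing notes the reads were processed with Salmon 0.13.1 (transcript quantification), DESeq2 1.38.3 and hg38; the role and order of each step were not given in the sources used here. The authors also deposited a second table, treated here as normalized signal. Its values equalled the counts divided by 1 factor per library, from 0.600 to 1.46, and these factors matched DESeq2 median-of-ratios factors computed from the counts. That table was used only for this check. Strand use in counting was not given in the sources used here, so values of overlapping or antisense genes cannot be separated, and near-identical gene copies may share reads.

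The table held 60669 gene identifiers, of which 25271 had a count of 0 in all libraries. Of these identifiers, 60415 matched the table of gene names, 42052 had a symbol and 58482 had a GENCODE release 29 position on hg38. The 45 entries for the Y copy of the pseudoautosomal region, with 119650 counts in all, were tested under their own identifiers. Total counts per library ran from 12404270 to 28801579. A count of 0 in 1 library allows up to 3 counts, which is 0.104 to 0.242 CPM, and such limits and all counting intervals cover counting error only. No pair of replicates was a duplicate, since the chi-square per degree of freedom between replicates ran from 2.65 to 17.0.

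Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups, with a minimum count of 10 and a minimum total of 15, which left 16393 genes. Libraries were scaled by TMM, and CPM below means TMM-scaled counts per 1e+06 counts. A single quasi-likelihood model with robust dispersion was fitted to all 12 libraries with 1 mean per group and no covariate. The 6 contrasts were the guide effect in untreated cells, with IFNB and averaged over both treatments, the IFNB response in GFP and in LTR8B cells, and the interaction of guide and IFNB. Benjamini-Hochberg adjustment was made over the tested genes at a threshold of 0.05, and adjusted p below means this value unless another tool is named. SE is the standard error of the log2 fold change. The guide effects in the 2 treatments share no library, and neither do the IFNB responses in the 2 lines.

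The design, the alternatives, the 25 gene lists and the rule for named genes were fixed before the data were examined. Named genes were SP140, SP140L, SP110 and SP100 in every comparison; the 10 largest increases and decreases per comparison among genes past the threshold with a symbol, a mean CPM of at least 1 and no overlap between groups; up to 4 members per described list with the smallest adjusted p; and the 10 genes with the smallest adjusted p in the interaction. The lists covered core interferon-stimulated genes, interferon signalling, negative regulators of interferon signalling, antigen presentation, MHC class II, NF-kB and inflammatory genes, interferons and their related factors, speckled and nuclear body proteins, neighbours of SP140, HOX genes, chromatin silencing, extracellular matrix and mesenchymal genes, cell cycle, p53 targets, integrated stress and unfolded protein response, hypoxia and glycolysis, cholesterol and lipid synthesis, immediate early genes, heat shock, mitochondrially encoded genes, ribosomal proteins, replication histones, and markers of epithelial, haematopoietic and neural cells.

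Lists were tested with limma 3.58.1, using camera with a preset correlation of 0.01 and, beside it, an estimated correlation, and fry, with adjustment over the 25 lists. An interferon score was the mean of log2(CPM + 1) over the core interferon list per library. Score and SP140 family differences were tested by exact two-sided permutation of guide labels within each treatment, over all arrangements. Within 1 treatment the 15 arrangements cannot give a p below 0.0667. Intervals for ratios over 1 to 3 counts are exact, at 95% confidence. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for summaries and figures.

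The model was tested on simulated data with 200 changed genes per contrast. Simulated libraries were drawn independently, without the pairing of libraries described below, so recovery in the real data may differ. At a log2 change of 1 it recovered 36 of 50 for the guide effect in untreated cells, 34 of 50 with IFNB, 41 of 48 averaged over treatments, 36 of 50 for the IFNB response in each line and 35 of 50 for the interaction. At a log2 change of 0.5 the interaction recovered 15 of 50 (16333 genes in that test), and false calls were between 1.96% and 7.18% of all calls over the 6 contrasts.

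Replicate numbers were checked as pairs. Deviations from the group means of same-numbered LTR8B libraries, untreated and IFNB, correlated at 0.226, 0.179, 0.132 and 0.214. Differently numbered LTR8B libraries reached at most 0.0583. GFP IFNB replicate 2 and LTR8B untreated replicate 3, which share no guide, treatment or number, reached 0.357, so correlations of this size do not by themselves mark pairs. The numbers may thus pair the LTR8B libraries, by a pattern in the data and not by the labels. A replicate block was therefore fitted as an alternative. The permutations of guide labels do not keep these pairs together, so their p-values for differences averaged over treatments may be too small. Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios factors, library totals alone, no low-count filter, a filter at a CPM of 1 in 4 libraries, only the compared groups in the fit, the replicate block, other pseudocounts and a median for the score, and leaving out each library. A guide-specific replicate block and blocked list tests were added after seeing the data. SP140 reads were not split by transcript, and the position of the guide and of the LTR8B element was not used here.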

Results

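RNA from 12 HT1080 libraries was measured as counts per gene. The 2 GFP untreated libraries held 26042371 and 20907005 counts, and the 2 GFP IFNB libraries 21477276 and 20153678. The 4 LTR8B untreated libraries held 21318625, 19354070, 28801579 and 19495336 counts, and the 4 LTR8B IFNB libraries 19951681, 21772444, 12404270 and 19411430. Mitochondrially encoded genes took 3.35% to 4.55% of the counts per library. The first principal component held 31.9% of the variance between libraries and separated treated from untreated libraries, and the second held 11.9%. GFP cells and LTR8B cells below are cells with the GFP guide and with the LTR8B guide.

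The first comparison asked how far the LTR8B guide lowered SP140, the gene that carries the targeted element. SP140 (ENSG00000079263.19, a bromodomain protein of nuclear bodies) lies on chromosome 2 at 230203110 to 230313215 on hg38, plus strand, and its main transcripts have a first intron at 230225904 to 230237082. In untreated cells SP140 was at 30.3 ± 0.728 CPM with the GFP guide (SD, n = 2) and at 1.25 ± 0.570 CPM with the LTR8B guide (SD, n = 4), which is 4.13% of the GFP level. With IFNB it was at 30.9 ± 1.56 CPM (SD, n = 2) and 1.23 ± 0.288 CPM (SD, n = 4), or 3.98%. The log2 fold change was -4.55 untreated (SE 0.20, edgeR adjusted p = 3.18e-09) and -4.67 with IFNB (SE 0.21, edgeR adjusted p = 3.33e-09). All 8 LTR8B libraries, from 0.515 to 1.84 CPM, lay below all 4 GFP libraries, and the exact permutation p was 0.00444, the smallest that the arrangements of the guide labels can give. These arrangements do not keep the paired LTR8B libraries together, so this p may be too small. IFNB left no difference in SP140 past the threshold, with log2 fold changes of 0.03 in GFP cells (adjusted p = 0.966) and -0.09 in LTR8B cells (adjusted p = 0.961).

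SP110, an interferon-induced nuclear body protein encoded next to SP140 on the opposite strand (chromosome 2, 230167293 to 230225729), was also lower with the LTR8B guide. Its level in untreated cells was 26.2 ± 1.87 CPM with the GFP guide (SD, n = 2) and 17.0 ± 1.66 CPM with the LTR8B guide (SD, n = 4), or 65.2%. The log2 fold change was -0.62 (SE 0.09, edgeR adjusted p = 0.00144). With IFNB SP110 was at 202.5 ± 4.33 CPM and 173.5 ± 9.12 CPM, or 85.7%, a log2 difference of -0.22 that did not pass the threshold (SE 0.08, edgeR adjusted p = 0.344). Averaged over treatments SP110 fell by 0.42 on the log2 scale (SE 0.06, edgeR adjusted p = 4.94e-04, exact permutation p = 0.00444). The limit given for the permutation p of SP140 holds here too. The difference between the treatments was 0.40 (SE 0.12, adjusted p = 0.996). Without GFP untreated replicate 1 the untreated call ended (adjusted p = 0.0845).

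SP140L and SP100, paralogs of SP140 downstream on the same strand, did not pass the threshold in any guide comparison. SP140L was at 42.4 ± 2.46 CPM in GFP and 42.0 ± 2.79 CPM in LTR8B untreated cells, and at 78.4 ± 7.79 and 82.0 ± 4.53 CPM with IFNB (exact permutation p = 0.689). SP100, a scaffold protein of PML nuclear bodies, was at 99.01 ± 1.75 and 94.96 ± 3.32 CPM untreated and at 286 ± 1.09 and 284 ± 12.9 CPM with IFNB (exact permutation p = 0.267). Other genes within 1 Mb of SP140 with a mean CPM of at least 1 did not pass either. The differences nearest the threshold, averaged over treatments, were 0.29 for PID1 (SE 0.08, edgeR adjusted p = 0.0668), -0.52 for FBXO36 (SE 0.15, edgeR adjusted p = 0.0932) and 0.22 for ARMC9 (SE 0.06, edgeR adjusted p = 0.0951), which were picked after their values were seen. Of the 13 tested neighbours on the fixed list, SP110 was the only one past the threshold untreated and averaged. Adjusted over the list alone, PID1 was also higher and FBXO36 also lower in both of these, and ARMC9 higher in the average.

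**Figure D1:**
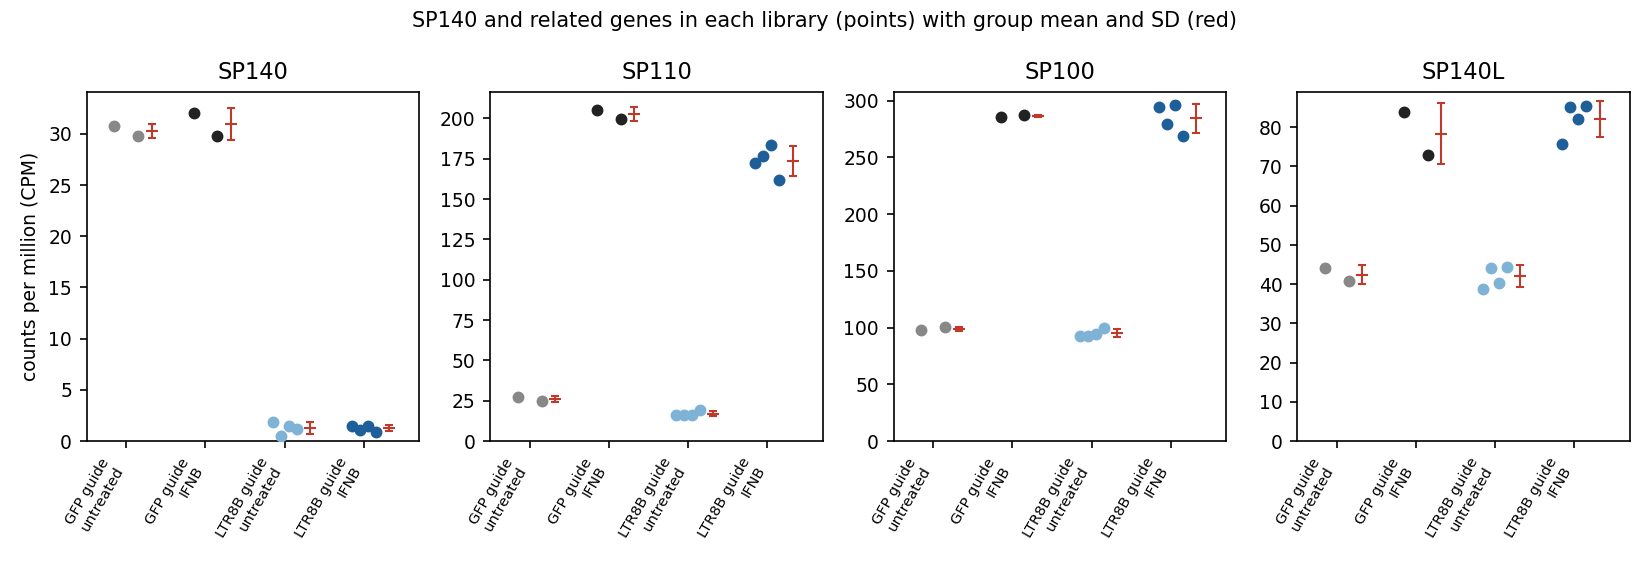
Level of SP140, SP110, SP100 and SP140L in each of the 12 libraries (CPM, points) by group, with the mean and SD in red. Points are grey for GFP untreated, black for GFP IFNB, light blue for LTR8B untreated and dark blue for LTR8B IFNB. SP140 lies at 1.84 CPM or below in all 8 LTR8B libraries and near 30 CPM in the 4 GFP libraries, while the other 3 genes rise with IFNB in both lines.

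**Figure D2:**
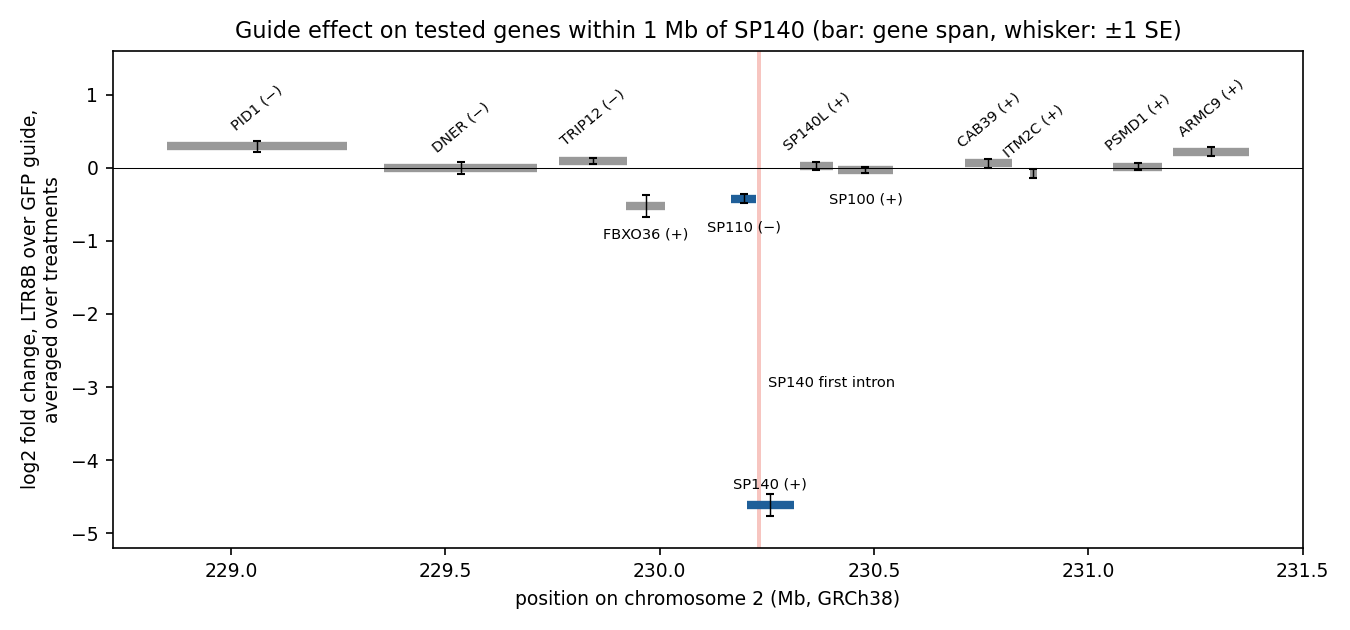
Guide effect (log2 fold change, LTR8B minus GFP, averaged over treatments) against position on chromosome 2 (Mb) for genes within 1 Mb of SP140 with a mean CPM of at least 1. Bars span each gene, whiskers are 1 SE, blue marks genes past the threshold (SP140 at -4.61 and SP110 at -0.42) and the pink band is the first intron of SP140.

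In untreated cells 59 of 16393 genes differed between the guides, 40 higher and 19 lower with the LTR8B guide. Genes far from SP140 differed as well. The smallest adjusted p was that of LRCH3, which encodes a protein with leucine-rich repeats. LRCH3 rose from 12.7 ± 0.662 CPM (SD, n = 2) to 55.3 ± 1.96 CPM (SD, n = 4), a log2 fold change of 2.13 (SE 0.08, edgeR adjusted p = 9.22e-11). SLC25A46, a mitochondrial outer membrane protein, rose from 19.7 ± 0.441 to 95.6 ± 12.95 CPM, and ZWILCH, a kinetochore protein, from 20.3 ± 2.16 to 72.9 ± 4.06 CPM. FRG2 fell by 2.96 (SE 0.33, edgeR adjusted p = 0.00133), from 16.4 ± 5.18 to 2.08 ± 0.921 CPM. It belongs to a family of near-identical copies whose reads may be shared. The secreted guidance factor SEMA3B fell by 1.21.

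Among the other genes picked by the rule in untreated cells, log2 increases were 3.52 for FAM124A, 2.87 for SUSD2, 2.58 for C19orf33, 2.30 for the histone gene H2BC15, 2.25 for HSD3B7, an enzyme of bile acid synthesis, 2.14 for the pseudokinase PRAG1 and 1.74 for TRIM52-AS1. TRIM52-AS1 and TRIM52 start 73 bp apart on opposite strands, so only reads near that start could be shared. H2BC15 is 1 of many similar histone genes, so its reads are uncertain. Lower genes included the noncoding RNA LINC01411 (-1.52), LSP1, an actin-binding protein of leukocytes (-1.54), HSD11B1, which converts cortisone to cortisol (-1.26), VGF, a neuropeptide precursor (-0.73), and PARP16, an ADP-ribosyltransferase (-0.50). From the fixed lists, the basement membrane collagen COL4A1 (0.42), the matrix protein THBS1 (0.46) and the collagen chaperone SERPINH1 (0.43) rose.

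All 59 genes showed no overlap between the groups, where chance gives 13.3% of unselected genes. Genes past the threshold are picked from the same libraries, so here and below such counts follow in part from that choice. DESeq2 gave 179 genes (111 higher and 68 lower, 58 of the 59 among them) and the fit with no low-count filter 325 (175 higher and 150 lower, also 58 of the 59). The count was 34 without GFP untreated replicate 1, 22 without GFP untreated replicate 2 and 94 without LTR8B untreated replicate 2. Of the 23 named genes past the threshold, 11 stayed past it without each library in turn. Leaving out GFP untreated replicate 2 ended the calls of LINC01411 (adjusted p = 0.107), SEMA3B (0.119), COL4A1 (0.194), SERPINH1 (0.258), THBS1 (0.338), SUSD2 (0.438), LSP1 (0.153), HSD11B1 (0.529), VGF (0.157) and PARP16 (0.119). Leaving out GFP untreated replicate 1 ended SUSD2 (0.237), THBS1 (0.0985), SERPINH1 (0.284), LSP1 (0.346), VGF (0.110) and PARP16 (0.322). HSD11B1, LSP1 and PARP16 were further lost without several other libraries, and LSP1 (0.108), VGF (0.0774) and PARP16 (0.135) under a replicate block, HSD11B1 (0.0672) without the low-count filter and SUSD2 (0.0733) with limma-voom.

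With IFNB 58 genes differed between the guides, 38 higher and 20 lower in LTR8B cells. LRCH3 rose from 13.3 ± 0.637 CPM (SD, n = 2) to 55.9 ± 1.47 CPM (SD, n = 4), a log2 fold change of 2.07 (SE 0.08, edgeR adjusted p = 1.65e-10). FAM124A rose by 3.69, C19orf33 by 3.68, HSD3B7 by 2.54, H2BC15 by 2.46, PRAG1 by 2.33, TRIM52-AS1 by 2.09, SLC25A46 by 2.06, ZWILCH by 1.74 and MSRB1, a methionine sulfoxide reductase, by 1.83. FRG2 fell by 3.04, endothelial lipase (LIPG) by 2.03, the lysosomal membrane protein LAPTM5 by 1.29, the cartilage matrix protein CILP by 1.02, SEMA3B by 0.98, the retinoic acid binding protein CRABP2 by 0.96 and VGF by 0.85, and LINC01411 fell to a similar degree as in untreated cells (edgeR, past the threshold). Core interferon-stimulated genes were at much the same level in both treated lines. Of the 60 tested, 0 passed the threshold by edgeR (9 at an unadjusted p under 0.05) or limma-voom (11) and 1 by DESeq2 (the antiviral GTPase MX2, log2 difference -0.59, DESeq2 adjusted p = 0.0141; 8 at an unadjusted p under 0.05), although 50 had a negative fold change, with a median of -0.10 (camera adjusted p = 2.35e-06, adjusted p = 0.785 with an estimated correlation, fry adjusted p = 0.484). Adjusted over the list alone MX2 was lower by edgeR too.

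The matrix list had 2 members higher with IFNB, COL4A1 (0.33) and THBS1 (0.44), and adjusted over the list alone 4 higher and 2 lower. SERPINH1 (0.43) and the actin-bundling protein LCP1 (0.38) also rose. All 58 genes showed no overlap between the groups (13.3% of unselected genes by chance). DESeq2 gave 119 genes (85 higher and 34 lower, 56 of the 58 among them), and with no low-count filter the balance turned, with 260 genes, 118 higher and 142 lower (57 of the 58). The count was 21 without GFP IFNB replicate 2 and 37 without LTR8B IFNB replicate 2. Of 24 named genes past the threshold, 11 stayed past it without each library in turn. GFP IFNB replicate 2 was decisive for FRG2 (adjusted p = 0.0523 without it), LIPG (0.305), LINC01411 (0.147), LAPTM5 (0.520), CILP (0.520), SEMA3B (0.321), CRABP2 (0.131), COL4A1 (0.151), LCP1 (0.694), SERPINH1 (0.268) and THBS1 (0.321), and GFP IFNB replicate 1 for VGF (0.0527). A replicate block, whose numbers do not pair these groups, ended the calls of LIPG (0.0547), SEMA3B (0.0640) and COL4A1 (0.0721).

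Averaged over treatments, 351 genes differed between the guides, 188 higher and 163 lower in LTR8B cells, with 25 higher and 35 lower by at least 2-fold. FAM124A, at 0.801 ± 0.599 and 0.683 ± 0.0892 CPM in GFP cells and 8.85 ± 0.902 and 8.91 ± 1.82 CPM in LTR8B cells untreated and with IFNB, had a log2 fold change of 3.60 (SE 0.22, edgeR adjusted p = 6.55e-08). Further increases were 2.10 in LRCH3 (SE 0.06, edgeR adjusted p = 4.16e-13), 2.17 in SLC25A46 (SE 0.08, edgeR adjusted p = 2.70e-11), 2.24 in PRAG1 (SE 0.08, edgeR adjusted p = 1.40e-11) and 1.79 in ZWILCH (SE 0.07, edgeR adjusted p = 2.72e-11). FRG2, at 2.08 ± 0.921 and 1.499 ± 0.666 CPM in LTR8B cells, fell as well (SE 0.25, edgeR adjusted p = 4.40e-05), LIPG fell by 1.82, LINC01411 by 1.56, prostaglandin E synthase (PTGES) by 1.41, LSP1 by 1.34 and HSD11B1 by 1.20. KIR3DX1 (-1.68) and LAIR2 (-1.47), a soluble collagen receptor of leukocytes, fell as well, but their calls ended without any 1 of the 4 GFP libraries for KIR3DX1 (adjusted p from 0.0921 to 0.149) and without GFP untreated replicate 1 (0.0674) or 2 (0.124) or GFP IFNB replicate 2 (0.122) for LAIR2.

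The extracellular matrix list moved both ways in the average. Of 38 tested members 5 rose (COL4A1, COL4A2, COL12A1, THBS1 and the mesenchymal transcription factor SNAI2) and 4 fell (COL1A1, SPARC, PLAU and CDH11), and adjusted over the list alone 8 rose and 9 fell. COL4A1 was at 208 ± 7.55 and 220 ± 8.82 CPM in GFP cells and 278 ± 10.2 and 276 ± 9.76 CPM in LTR8B cells (log2 fold change 0.38, SE 0.04, edgeR adjusted p = 1.05e-04). COL4A2 rose by 0.27, THBS1 by 0.45 and SNAI2 by 0.63. COL12A1 (0.22), COL1A1 (-0.64), SPARC (-0.22), PLAU (-0.29) and CDH11 (-0.41) were chosen after their values were seen. Each call ended without GFP untreated replicate 2 or GFP IFNB replicate 2, which leaves 1 library in a group. The COL1A1 call ended without any 1 of the 12 libraries, with an adjusted p from 0.0546 to 0.0935 without an LTR8B library. CDH11, COL12A1 and SPARC were also lost without several LTR8B libraries left out in turn. In the cholesterol list 1 member rose and 3 fell, 2 of them SQLE and FDFT1, enzymes of sterol synthesis that fell by 0.17 each. Adjusted over the list alone 1 rose and 10 fell of 28, and camera gave an adjusted p = 0.00316, with adjusted p = 0.678 with an estimated correlation.

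Markers of haematopoietic cells moved both ways too. LAPTM5 fell by 1.12 (edgeR adjusted p = 0.00154) and the receptor CSF1R by 0.57, and LCP1, at 864 ± 24.2 CPM in untreated GFP cells, rose by 0.32, while 7 of the 10 tested were not past the threshold (adjusted over the list alone 1 higher and 4 lower). SP140 and SP110 were the 2 of 10 nuclear body proteins past the threshold (adjusted over the list alone the same 2), and camera put the list lower (adjusted p = 0.0245, adjusted p = 0.364 with an estimated correlation). That list holds SP140 itself, the target of the guide, and of its 10 fold changes 4 were positive and 6 negative, with a median of -0.04. Single members of other lists passed, with the innate sensor adaptor STING1 lower (-0.30, list alone 2 higher and 3 lower in interferon signalling) and the p53 target FDXR lower (-0.30). Higher were the peptide-trimming enzyme ERAP1 (0.20), the secreted factor STC2 (0.30), the cell adhesion protein NCAM1 (0.38), SERPINH1 (0.43), the immediate early gene NR4A3 (0.71) and the histone gene H4C8 (0.57). In the ribosomal protein list 1 of 48 members passed, and it was higher (also 1 adjusted over the list alone), while 42 of 48 fold changes were negative (camera adjusted p = 3.94e-04, adjusted p = 0.873 with an estimated correlation).

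No member passed in the average by edgeR in the core interferon, negative regulator, MHC class II, NF-kB, interferon, HOX, chromatin silencing, cell cycle, hypoxia, mitochondrially encoded and epithelial lists. Adjusted over the list alone NFKB1 and CXCL8 were higher and TRAF1, ICAM1, TNFAIP2 and CCL5 lower in the NF-kB list, and HK2 and PFKFB3 higher and NDRG1 and VEGFA lower in the hypoxia list. DESeq2 put 1 core interferon gene (GBP1, higher) and 3 hypoxia genes (PFKFB3 higher, NDRG1 and VEGFA lower) past the threshold in the average, limma-voom 0 of either list, and edgeR had 7 core interferon and 5 hypoxia genes at an unadjusted p under 0.05. Of the 351 genes 324 showed no overlap between guides in both treatments (1.78% of unselected genes by chance). DESeq2 gave 566 genes (337 higher and 229 lower, 335 of the 351 among them) and the fit with no low-count filter 775 (393 higher and 382 lower, 339 of the 351). A replicate block, whose numbers do not pair libraries across guides, gave 181 (109 higher and 72 lower, 151 of the 351), and 39 of the 60 genes with a 2-fold difference stayed past the threshold. Each GFP library moved the count, which was 191 without untreated replicate 1, 93 without untreated replicate 2, 178 without IFNB replicate 1 and 153 without IFNB replicate 2. Of 41 named genes past the threshold, 25 stayed past it without each library in turn. Leaving out GFP untreated replicate 2 alone ended the calls of CSF1R (adjusted p = 0.0697) and LCP1 (0.0651), and NCAM1 was lost without GFP untreated replicate 2 (0.124) or GFP IFNB replicate 2 (0.0851). STING1, FDXR, SQLE, FDFT1, ERAP1, STC2, H4C8 and NR4A3 were each lost without at least 3 of the libraries, with their highest adjusted p, between 0.105 and 0.288, without 1 of the GFP libraries.

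**Figure D3:**
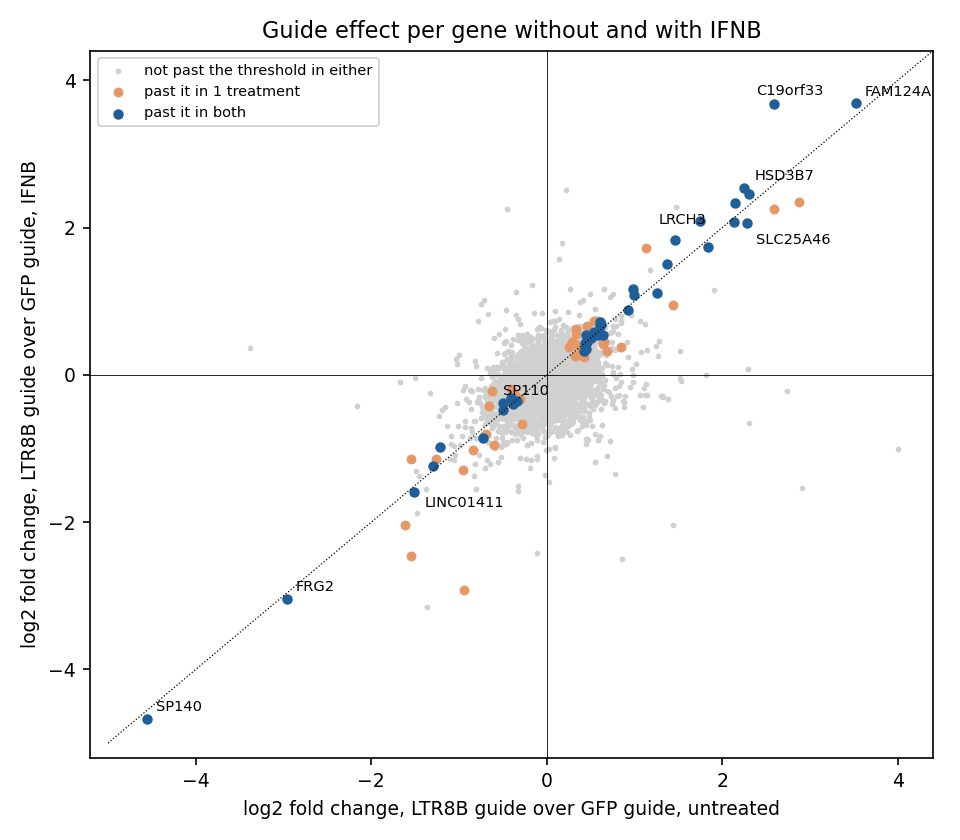
Guide effect (log2 fold change, LTR8B minus GFP) in untreated cells against that with IFNB, for genes with a mean CPM of at least 1. Coloured points are genes past the threshold; FAM124A, at 3.52 and 3.69, and SP140, at -4.55 and -4.67, lie at the ends of the diagonal.

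A further question was whether the guide effect was the same with and without IFNB. Of the genes past the threshold in each treatment, 40 were shared, 29 higher and 11 lower, where independent lists would share 0.209 (Fisher's exact p = 1.37e-91). That test takes genes and lists as independent. Both comparisons set the same 2 lines against each other, and same-numbered LTR8B libraries correlate across treatments. The p therefore does not measure how repeatable an effect of the guide is. SP140, LRCH3, SLC25A46, ZWILCH, PRAG1, HSD3B7, FAM124A and C19orf33 were among them. Across all tested genes, which are not independent replicates, the 2 effects correlated at Pearson r = 0.0955 and Spearman 0.280, with the same sign in 61.0% of genes. Over the 77 genes past the threshold in either, a set picked for large effects, r was 0.954. With only genes at a CPM of 1 or more in 4 libraries, r was 0.334.

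IFNB treatment of GFP cells asked for the interferon response of the control line. Here 524 genes changed, 502 higher and 22 lower, with 247 higher by at least 2-fold. The interferon-induced RNA-binding protein IFIT2 rose from 9.49 ± 1.44 to 2900 ± 210 CPM (SD, n = 2 each), a log2 fold change of 8.26 (SE 0.11, edgeR adjusted p = 3.56e-18). Other antiviral effectors followed, with log2 increases of 8.52 in MX2, 8.46 in XAF1, 8.36 in IFIT1, 8.06 in OASL, 7.70 in OAS2, 7.54 in IFI44L, 6.36 in IFIT3 and 4.88 in SAMD9. RSAD2, which makes an antiviral nucleotide, went from 1 count to 6224 counts in the 2 libraries, a ratio of 7224 (95% interval 1296 to 285400). The pseudogene GBP1P1, whose reads may be shared with GBP1, was at 0 counts untreated and at least 51.9-fold higher with IFNB, taking 3 counts over the untreated group as its floor.

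All 60 core interferon genes had a positive fold change, 58 of them past the threshold and all 60 adjusted over the list alone (median log2 fold change 3.57, camera adjusted p = 2.74e-04 with an estimated correlation). IFITM2 (adjusted p = 0.0525) and APOBEC3G (0.0768) were the exceptions. In the signalling list 13 of 24 rose (14 adjusted over the list alone), among them the RNA sensors RIGI (5.22) and IFIH1 (4.57) and the transcription factor subunit IRF9 (4.86). In antigen presentation 15 of 18 rose (18 adjusted over the list alone), among them the peptide transporter TAP1 (2.78), HLA-B (1.92), NLRC5, an activator of class I genes (1.89), and HLA-E (1.31). In the list named negative regulators of interferon signalling, USP18 (6.22), SOCS1 (1.99) and UBA7 (1.41) rose and 11 of 14 did not pass (adjusted p = 0.338 with an estimated correlation). Membership follows the fixed list and is not a finding on what each member does. Nuclear body proteins rose in 4 of 10 cases, SP110 by 2.95, PML by 2.11, SP100 by 1.53 and SP140L by 0.88, and HIRA was added when adjusted over the list alone. Of 13 tested neighbours of SP140 4 rose, these 3 SP family genes and the ubiquitin ligase TRIP12 (0.28), while adjusted over the list alone CAB39 was also higher and ARMC9 lower (adjusted p = 0.111 with an estimated correlation).

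Chemokines led the inflammatory list, in which CXCL10 (7.09), CXCL11 (5.93) and CCL2 (1.86) rose and 18 of 21 did not pass (6 adjusted over the list alone, adjusted p = 0.286 with an estimated correlation). Immediate early genes split, with KLF6 (0.80), IER2 (0.46) and ATF3 (1.12) higher and EGR1 (-0.59), MYC (-0.44) and IER3 (adjusted p = 0.0498) lower (5 higher and 3 lower adjusted over the list alone). Single members rose in the stress (ATF3), hypoxia (HK2, 0.50), cholesterol (STARD4, 0.91), heat shock (DNAJA1, 0.55) and neural (MAP2, 1.28) lists, and SNAI2 (-0.70) was the 1 matrix gene that fell. Lower genes outside the lists included GPATCH11, from 59.05 ± 0.833 to 29.2 ± 0.594 CPM (-1.02, edgeR adjusted p = 1.70e-06), NUDT4B (-1.22), a near copy of NUDT4 whose reads may be shared, SIPA1L2 (-0.76), SDHAF1, an assembly factor of succinate dehydrogenase (-0.74), and OXLD1 (-0.66).

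In GFP cells no member passed by edgeR in the HOX, chromatin, p53, MHC class II, interferon, replication histone, epithelial, haematopoietic, cell cycle, mitochondrial and ribosomal lists. DNMT3B and TOP1 of the chromatin list and CIITA of the MHC class II list were higher adjusted over the list alone. All 48 ribosomal protein genes had a negative fold change (median -0.12, camera adjusted p = 2.05e-08, adjusted p = 0.544 with an estimated correlation), and 33 of 40 cell cycle genes did (camera adjusted p = 0.0101, adjusted p = 0.642 with an estimated correlation). All 524 genes showed no overlap between the groups, where chance gives 33.3% of unselected genes. The count was 344 without GFP untreated replicate 1. Of 48 named genes past the threshold 32 stayed past it without each library in turn. NUDT4B, OXLD1, MYC, ATF3, EGR1 and SNAI2 were each lost without any 1 of the 4 GFP libraries (adjusted p up to 0.274, 0.251, 0.253, 0.205, 0.359 and 0.235), as was TRIP12 (up to 0.349), SIPA1L2 and STARD4 without 3 of them (up to 0.340 and 0.235), and CCL2, SDHAF1, IER2 and HK2 without 2 (up to 0.183, 0.138, 0.0924 and 0.0861).

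IFNB treatment of LTR8B cells asked for the same response after SP140 had been lowered. It changed 737 genes, 658 higher and 79 lower, with 248 higher by at least 2-fold. IFIT2 rose from 9.42 ± 0.438 to 2552 ± 31.7 CPM (SD, n = 4 each), a log2 fold change of 8.08 (SE 0.08, edgeR adjusted p = 1.50e-20). Log2 increases were 8.29 in OASL, 8.18 in IFI44L, 8.17 in MX2, 8.13 in IFIT1, 7.37 in OAS2, 7.31 in IFI27, 6.26 in IFIT3 and 4.70 in SAMD9. RSAD2 went from 3 to 9415 counts in the 4 libraries, a ratio of 3932 (95% interval 1345 to 19070), and CXCL10 from 3 to 1061 counts, a ratio of 443 (95% interval 151 to 2152). GBP1P1 went from 1 to 231 counts, a ratio of 289 (95% interval 51.4 to 11480).

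All 60 core interferon genes rose (60 adjusted over the list alone, median 3.46, camera adjusted p = 1.91e-04 with an estimated correlation). In signalling 15 of 24 rose (16 adjusted over the list alone), with RIGI at 5.06, IRF9 at 4.55 and IFIH1 at 4.54, and in antigen presentation 17 of 18 (18 adjusted over the list alone), with TAP1 at 2.85, the immunoproteasome subunit PSMB9 at 2.39, NLRC5 at 2.07 and HLA-E at 1.37. USP18 (6.21), SOCS1 (1.95) and UBA7 (1.56) were again the members of the negative regulator list that rose, and SOCS3 was added when adjusted over the list alone (adjusted p = 0.139 with an estimated correlation). Nuclear body proteins rose in 5 of 10 cases, SP110 by 3.35, PML by 2.04, SP100 by 1.58, SP140L by 0.97 and HIRA (6 of 10 adjusted over the list alone). TRIP12 (0.23) and the same 3 SP family genes were the 4 of 13 neighbours that rose, with CAB39 added when adjusted over the list alone (adjusted p = 0.0550 with an estimated correlation, 0.0415 with a guide-specific replicate block and 0.101 with a plain replicate block).

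In the inflammatory list 6 of 21 rose (CXCL10, CXCL11, CCL2, CCL5, IL6 and NFKBIA), and CXCL8 was lower adjusted over the list alone (adjusted p = 0.132 with an estimated correlation). CXCL11 rose by 6.60, CCL5 by 1.40 and CCL2 by 1.32. KLF6 (0.72), IER2 (0.34), ATF3 (1.15), ZFP36 and JUNB rose among immediate early genes, and EGR1 (-0.53), IER3 (-0.24) and MYC fell, while KLF2 and SPRY2 were lower adjusted over the list alone. The heat shock genes DNAJA1 (0.56), HSPA1A (0.52) and HSPA1B (0.42), the latter a near-identical pair, HK2 (0.41), STARD4 (0.61) and the DNA methyltransferase DNMT3B (0.42) rose. MAP2, a neuronal microtubule protein, rose by 1.03, and TUBB3 was added when adjusted over the neural list alone (camera adjusted p = 0.0469, adjusted p = 0.139 with an estimated correlation). SNAI2 (-0.48) and CCN1 (-0.42), a matrix-associated signalling protein, fell. The p53 targets BBC3 (0.35) and GDF15 (0.28) rose, with FAS added when adjusted over the list alone, and HOXB2 (-0.30) and HOXB9 (-0.21) fell. With a replicate block the calls of GDF15 (adjusted p = 0.0668), HOXB2 (0.0882) and HOXB9 (0.0578) ended.

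Other genes that fell in LTR8B cells were GPATCH11, from 50.9 ± 4.78 to 27.7 ± 1.47 CPM (-0.88, edgeR adjusted p = 9.80e-08), EYA1, a developmental transcriptional regulator (-0.67), filaggrin (FLG, -0.63), the splicing factor CENATAC (-0.57) and the readthrough transcript JMJD7-PLA2G4B (-1.08), whose reads may belong to its 2 parent genes. No member passed by edgeR in the MHC class II, interferon, cell cycle, mitochondrial, ribosomal, replication histone, epithelial and haematopoietic lists. All 13 mitochondrially encoded genes had a negative fold change (median -0.17, camera adjusted p = 6.15e-05, adjusted p = 0.343 with an estimated correlation). Of the 737 genes 712 showed no overlap between the groups (2.86% of unselected genes by chance), and 772 passed with a replicate block and 1040 with a guide-specific replicate block (817 higher and 223 lower). With library totals alone the split was 561 higher and 178 lower, with a median log2 shift of all genes of -0.06. Of 58 named genes past the threshold 44 stayed past it without each library in turn. GDF15, BBC3, HOXB2, HOXB9, EYA1, SNAI2, HSPA1A, STARD4, CENATAC and JMJD7-PLA2G4B were lost without 1 or more LTR8B libraries, with adjusted p up to 0.177, 0.114, 0.176, 0.163, 0.114, 0.111, 0.119, 0.0688, 0.0943 and 0.0538.

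**Figure D4:**
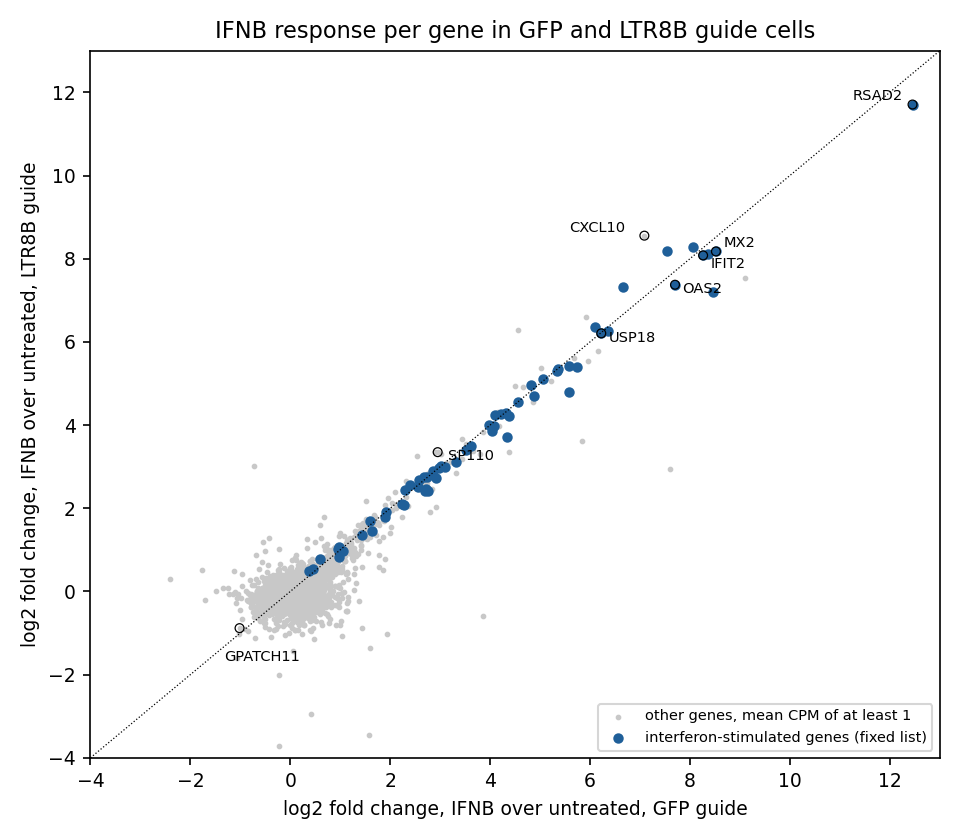
IFNB response (log2 fold change, IFNB minus untreated) in GFP cells against that in LTR8B cells, with the core interferon list in blue. The 60 core genes lie close to the diagonal, with Pearson r = 0.993 across genes.

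The series asked whether lowering the SP140-linked element alters the interferon response. The interferon score rose from 3.56 ± 0.0437 to 7.06 ± 0.0447 in GFP cells (SD, n = 2 each) and from 3.53 ± 0.0324 to 6.94 ± 0.104 in LTR8B cells (SD, n = 4 each). The rise was 3.50 in GFP and 3.41 in LTR8B cells, a difference of -0.09 that lay within the spread of the permuted labels (exact permutation p = 0.387). Across the 60 core genes, which are not independent replicates, the LTR8B response had a slope of 0.965 on the GFP response (bootstrap 95% interval over genes 0.929 to 1.01). The median difference of their responses was -0.07 (bootstrap 95% interval over genes -0.11 to -0.01), and 39 of 60 had a smaller response in LTR8B cells. Of the genes past the threshold, 463 were shared by both lines, 453 higher and 10 lower, where independent lists would share 23.6. Across all tested genes the responses correlated at Pearson r = 0.556 and Spearman 0.299, and at 0.797 over genes with a CPM of 1 or more in 4 libraries.

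The interaction, which tests the difference between the 2 IFNB responses gene by gene, gave 0 of 16393 genes past the threshold by edgeR, with 489 at an unadjusted p under 0.05. DESeq2 and limma-voom also gave 0, with 407 and 501 at an unadjusted p under 0.05. These numbers lie below 1 in 20 of the tested genes, the share that chance gives on average. Genes are not independent, and by edgeR the number was 343 without LTR8B untreated replicate 3 and 1129 without LTR8B untreated replicate 2. Whether the tests were conservative here can therefore not be told. A guide-specific replicate block, added after seeing the data, allows for the LTR8B pairs. It gave 4 genes, with 1027 at an unadjusted p under 0.05. The log2 differences of these 4 were -16.9, -9.63, 14.5 and -14.4. Differences of that size can come from counts near 0, which was not checked, so the 4 are not read as interaction genes. In the simulated data the interaction recovered 15 of 50 genes at a log2 change of 0.5. The 0 by edgeR thus does not show that the responses were equal. The smallest adjusted p was 0.996, shared by the genes with the lowest unadjusted p. Among these the histone methyltransferase KMT2D had a difference of -0.33 (SE 0.08), the transcription factor ZBTB20 of -0.66 (SE 0.17) and RGS17, a regulator of G protein signalling, of -0.70 (SE 0.20). With no low-count filter ZBTB20 passed (edgeR adjusted p = 0.0328), as 1 of 13 genes in that fit. SP140 (-0.12), SP140L (0.09) and SP100 (0.05) did not pass, and SP110 (0.40) passed only when adjusted over the list alone, in the nuclear body and neighbour lists. No other list had a member past the threshold either way. Without GFP untreated replicate 1 the gene NPIPA9, a member of a family of near-identical copies, passed (adjusted p = 0.0320).

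As sets, camera put 3 lists apart in the interaction. All 13 mitochondrially encoded genes had a positive IFNB fold change in GFP cells (median 0.10) and a negative one in LTR8B cells (median -0.17), a median difference of -0.30, though 0 of 13 passed by edgeR, DESeq2 or limma-voom (4, 6 and 4 at an unadjusted p under 0.05; camera adjusted p = 1.38e-10, adjusted p = 0.803 with an estimated correlation). All 48 ribosomal protein genes had a positive difference (median 0.15, camera adjusted p = 3.48e-16, adjusted p = 0.907 with an estimated correlation), as had 33 of 40 cell cycle genes (camera adjusted p = 6.42e-04, adjusted p = 0.907 with an estimated correlation). In the guide comparison of untreated cells 46 of 48 ribosomal fold changes were negative (camera adjusted p = 6.89e-13, adjusted p = 0.621 with an estimated correlation), as were 32 of 40 cell cycle ones (camera adjusted p = 0.0239, adjusted p = 0.926 with an estimated correlation). All 13 mitochondrial fold changes were positive there (camera adjusted p = 0.00209, adjusted p = 0.621 with an estimated correlation) and negative in the guide comparison with IFNB (camera adjusted p = 0.00170, adjusted p = 0.785 with an estimated correlation). Ribosomal and cell cycle genes did not stand apart with IFNB (camera adjusted p = 0.487 and 0.342). The core interferon list did not stand apart (camera adjusted p = 0.190).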

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

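The tests of reads shared between SP140 and SP110 and of the genes around SP140 were chosen after the SP110 result was seen.

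In the groups of 4 libraries, 256 sets of values were examined for a library far from the other 3, and 13 held one. Chance gives about 1 in 20, so this number is close to what chance alone gives. LTR8B IFNB replicate 4 was low in SERPINH1 (75.3 CPM, others 86.9 to 88.5), UBA7 (14.4, others 19.1 to 19.8), NLRC5 (71.2, others 86.4 to 88.9), FLG (5.25, others 5.78 to 5.87) and IFIT3 (1661, others 1682 to 1686). LTR8B untreated replicate 4 was high in SP110 (19.5 CPM, others 16.1 to 16.3), NR4A3 (10.8, others 7.38 to 7.78) and CCN1 (598, others 542 to 550) and low in BBC3 (38.4, others 43.3 to 43.8). LTR8B untreated replicate 3 held all RSAD2 counts of its group (0.101 CPM, others 0), as LTR8B untreated replicate 2 did for GBP1P1 (0.0515 CPM, others 0). LTR8B IFNB replicate 1 was high in TRIP12 (499 CPM, others 484 to 486) and replicate 2 in COL12A1 (83.7, others 76.8 to 77.0). No biological explanation was tested for these libraries.

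By a test of the difference itself with a preset correlation, the IFNB responses of mitochondrially encoded genes (camera adjusted p = 1.38e-10), ribosomal protein genes (3.48e-16) and cell cycle genes (6.42e-04) differed between the 2 lines as sets, but with a correlation estimated from the data none did (0.803, 0.907 and 0.907). Of the 13, 48 and 40 members 0 passed by edgeR, DESeq2 or limma-voom (at an unadjusted p under 0.05 by edgeR 4, 2 and 0). The share of counts from mitochondrially encoded genes was lower with IFNB in all 4 same-numbered LTR8B pairs, from 3.86% to 3.40%, 3.98% to 3.69%, 3.96% to 3.35% and 4.55% to 3.97%, and was 3.78% and 4.10% in the GFP IFNB libraries. LTR8B untreated replicate 4 was the highest of its group in this share and GFP IFNB replicate 2 the higher of its 2.

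SP110 was lower with the LTR8B guide, and 2 technical explanations were weighed. If SP140 reads had been counted to SP110, the loss would follow SP140, which changed by 0.651 ± 1.22 CPM with IFNB in GFP cells (SE). SP110 instead lost 9.10 ± 1.57 CPM untreated and 28.9 ± 5.49 CPM with IFNB, a difference of 19.8 ± 5.71 CPM (SE). These SEs come from the group SDs, with n = 2 in each GFP group. In the edgeR fit the loss with IFNB did not pass the threshold (log2 difference -0.22, SE 0.08, edgeR adjusted p = 0.344). The values therefore argue only weakly against a fixed share of SP140 reads. Repression reaching most genes within 1 Mb of SP140 was argued against by the median log2 fold change of the other 10 genes there, 0.0189 (bootstrap 95% interval over genes -0.0433 to 0.138). Single genes moved either way, as given above for FBXO36 and PID1. A median cannot bear on repression that reaches only SP110 or single genes, so short-range spreading stays open. SP110 and SP140 start next to each other on opposite strands, so an effect of the guide on a shared start region may lower both, which stays open and was not tested.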

How the results depend on the processing

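The guide-specific replicate block and the blocked list tests were chosen after seeing the data; all other alternatives were planned. SP140 kept its direction and its side of the threshold under every alternative run, with log2 fold changes without 1 library from -4.76 to -4.33 untreated and -4.79 to -4.54 with IFNB.

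DESeq2 gave 179 genes for the guide effect untreated, 119 with IFNB and 566 averaged, and no low-count filter gave 325, 260, 775 and, for the interaction, 13. A replicate block gave 181 for the averaged guide effect. A guide-specific replicate block gave 4 for the interaction, H3P6, MIR3648-2 and 2 genes without a symbol, chosen after their values were seen. Those 4 had log2 differences from -16.9 to 14.5, a size that counts near 0 can give. The guide-specific replicate block gave 747 genes for IFNB in GFP cells, 664 higher and 83 lower, and 1040 in LTR8B cells, 817 higher and 223 lower. The correlation of guide effects between treatments was 0.334 with a filter at a CPM of 1 in 4 libraries, 0.235 with a replicate block and 0.297 with only the compared groups. That of the IFNB responses was 0.119 with DESeq2, 0.0783 without a filter, 0.797 with the CPM filter and 0.802 with only the compared groups. The lower core interferon list with IFNB was lost with an estimated correlation (0.785) and with fry (0.484), and the lower nuclear body list in the average with an estimated correlation (0.364). For IFNB in LTR8B cells the neighbour list passed with an estimated correlation under the guide-specific replicate block (0.0415), not without it (0.0550), and the blocks changed no other list call. The cause was not tested.

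Without 1 library the counts ran from 22 to 94 untreated, 21 to 69 with IFNB, 93 to 461 averaged, 344 to 594 for IFNB in GFP cells and 0 to 1 for the interaction. A lone library left in a GFP group is assumed to vary like the other groups. Over named genes and alternatives, 11185 results were the same, 347 lost and 26 gained a call, 447 values without a call moved, and 0 named calls reversed.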

Other observations

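The tests of single GFP libraries, shared start regions, chance, scaling and splits of the samples were chosen after the results were seen. The genes in the next paragraph were also chosen after their values were seen.

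IFNB raised genes outside the fixed lists in both lines. SAMHD1, which depletes nucleotides needed by viruses, rose from 26.1 ± 0.374 to 249 ± 4.68 CPM in GFP cells (SD, n = 2) and from 26.4 ± 1.39 to 232 ± 17.9 CPM in LTR8B cells (SD, n = 4). The log2 increases in GFP and LTR8B cells were 6.16 and 5.78 for the lysosomal transporter SLC15A3, 5.96 and 5.53 for the death ligand TNFSF10, 4.18 and 3.99 for APOL6, and 2.76 and 2.83 for the DNA sensor AIM2. Of the genes that IFNB changed in LTR8B cells, 384 had a gene changed the same way within 1 Mb, where the central 95% of 10000 random sets gave 301 to 359 (highest 388, share as large 4e-04), so clusters along the chromosomes went beyond that interval. The GBP genes on chromosome 1, the IFIT genes on chromosome 10, the APOL genes on chromosome 22 and 19 genes from HLA-F to BAK1 on chromosome 6 were among them. For the averaged guide effect 75 genes had such a neighbour, within the 47 to 85 of the central 95% of random sets (highest 106).

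Only 1 of the 35 splits of the 8 LTR8B libraries gave as many genes as IFNB treatment, the real one (737, highest other 3). Every other split puts treated and untreated libraries in the same group. A treatment effect then widens the spread within groups and lowers the count, so the contrast is in part built in. Replicate numbers may pair these libraries, and 8 splits part every such pair, too few for a share under 0.05, with 737 genes in the real one and 0 in the highest other. For the averaged guide effect 1 of 60 drawn splits gave as many, the real one (351, highest other 11). These splits were drawn within each treatment and do not keep the pairs of LTR8B libraries together. The other splits also mix libraries of both guides within a group, which lowers their counts in the same way. They do not settle whether chance is excluded.

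The 60 genes that differed by at least 2-fold between the guides, among them LRCH3, SLC25A46, PRAG1 and FRG2, were weighed next. Gain or loss of chromosome segments was argued against by their neighbours within 1 Mb, whose median signed log2 fold change was 0.00597 (bootstrap 95% interval over genes -0.0164 to 0.0162), although this does not bear on changes of single genes. Without any 1 GFP library 100% of the 60 genes kept a log2 fold change of at least 0.8 in the same direction. They were picked for a 2-fold average over these same libraries, so this follows in part from that choice. It does not decide whether a single GFP library drives the calls, and many of the 60 calls ended without any 1 of the GFP libraries. Genes that start within 1 kb on the opposite strand had a median signed log2 fold change of 0.241 (bootstrap 95% interval 0.00307 to 1.47, 6 pairs, 1 of them, AGPS and ENSG00000213963.6, between 2 of the 60), which leaves an effect at a shared start region undecided. Each guide is confounded with its line, so effects of either guide elsewhere in the genome and differences between the lines could not be separated.

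The smaller rise of the interferon score in LTR8B cells, by 0.09, may be chance, since the exact permutation p was 0.387. Scaling between libraries was argued against as the whole cause, as 91.0% of the difference was left under 1 other scaling and 105.5% under the other. An effect of lower SP140 on the interferon response stays open and is not shown by these data.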
